A study of Homo sapiens with 48 samples.

How the data were processed

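RNA was measured by paired-end sequencing of ribosomal RNA-depleted total RNA from 48 libraries of Flp-In 293 T-REx cells, a human embryonic kidney line with a single recombination site for inserting a transgene. Per the labels, 8 stable lines were used: a line carrying the CLIP tag alone (called CLIP below), a line expressing CLIP-tagged wild-type UPF1 (WT), and 6 lines expressing CLIP-tagged UPF1 mutants labelled F192E, FE-ER, I757R, IR-ER, E797R and LECY. The labels FE-ER and IR-ER share letters with the single mutants F192E, I757R and E797R, and LECY is not spelled out, so these 3 names are used as labels without a meaning. Each line was reverse-transfected with 40 nM of a non-targeting siRNA (siNT) or of an siRNA against UPF1 (siUPF1) and harvested after 72 h, in 3 replicates per line and siRNA, which the series' design text calls biological replicates. Per the labels' protocols, RNA was purified with TRIzol and treated with DNase, ribosomal RNA was removed with antisense oligonucleotides and RNase H, and libraries were made with the xGen RNA kit. Neither the siRNA sequences nor a doxycycline treatment were given in the sources used here.

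The deposited table held RSEM expected counts for 58870 genes in each of the 48 libraries, and 9.16% of its values were not whole numbers. The authors trimmed reads with cutadapt, aligned them with STAR to hg38, estimated counts with RSEM and used DESeq2, per the submitters' processing notes, which name the tools without their order, roles or versions. The annotation release and the strand setting of the counting were not given in the sources used here. Reads from a gene and an antisense or overlapping partner, or from a pseudogene and its parent, can therefore not be told apart with certainty, and RSEM divides reads that match several genes by estimation. Reads of the UPF1 transgenes and of endogenous UPF1 were summed at the UPF1 gene. Gene positions and types came from GENCODE 29 (hg38), matched by Ensembl ID for 16667 of the 16697 genes tested.

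Expected counts were rounded to whole numbers. Library totals ranged from 6016999 to 14551820 expected counts with a median of 8670884. In a library 21386 to 24383 genes had counts, and the 10 most abundant genes took 5.24% to 7.56% of a library. Genes were kept by edgeR's filterByExpr on the 16 groups with a minimum count of 10, which left 16697 genes. All 48 libraries entered 1 model with 16 groups (edgeR 4.0.16 in R 4.3.3, TMM factors between 0.951 and 1.03, robust quasi-likelihood fit), and contrasts were tested with edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment over the genes tested in each contrast. A gene was called at an adjusted p under 0.05. Levels are CPM, counts divided by TMM-scaled library sizes, given as mean ± SD over 3 replicates. The SE of a log2 fold change was its size divided by the square root of the F statistic. All adjusted p-values of single genes are from this edgeR test unless another tool is named, and all tests were two-sided. With 3 replicates against 3, an exact permutation test cannot give a p below 0.1.

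The contrasts were siUPF1 against siNT in each of the 8 lines, WT against CLIP and each of the 6 mutants against WT with siNT and again with siUPF1, and the differences of knockdown effects between the same pairs of lines. In 4 further contrasts, the knockdown effect of FE-ER was compared with those of F192E and E797R, and that of IR-ER with those of I757R and E797R. The UPF1-repressed set was defined as the 1571 genes at least 1.5-fold higher with siUPF1 than with siNT in CLIP. The response of a line was the mean log2 CPM (prior count 2) over the set with siUPF1 minus that with siNT, and its SD came from the 3 replicates of both siRNAs. For differences between lines, the response of each line was taken within replicate numbers, and the lines were then compared as independent groups of 3, with an SD from the SDs of both lines.

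Gene lists were tested with camera (limma 3.58.1; preset correlation 0.01, then an estimated correlation) and fry, with Benjamini-Hochberg adjustment over the 18 lists of a contrast. They were established targets of nonsense-mediated decay (NMD), NMD factors, the exon junction complex, snoRNA host genes, splicing factors with poison exons, ATF4 integrated stress response genes, unfolded protein response genes, p53 targets, replication-dependent histones, cell division, DNA replication, interferon response, selenoproteins, mRNA decay enzymes, cytosolic ribosomal proteins, cholesterol synthesis, mitochondrially encoded mRNAs and abundant structural RNAs. Some lists share members with the NMD target list, so their tests are not independent of it. The snoRNA host list shares GAS5, SNHG1, SNHG12, SNHG15, SNHG16, ZFAS1 and EIF4A2. The stress response list shares ATF4, ATF3, DDIT3, PPP1R15A, SLC7A11, CARS and STC2. Named genes were UPF1, the 10 largest rises and falls in the CLIP knockdown, the 4 largest in each other contrast, and in each list the 4 members with the smallest p. Values of some named list members are not reported here. The genes of largest change had to pass the threshold, average at least 5 CPM over the 6 libraries, not overlap between groups and carry a gene symbol other than a clone or LINC name. Groups, contrasts, tests, lists, this rule and most alternatives were fixed before the data were examined.

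Replicate numbers come from the sample titles. Across genes, the deviations of same-numbered libraries from their group means correlated with a mean r of 0.178 to 0.35 per contrast, and those of libraries with other numbers with −0.173 to −0.09. Deviations from a group mean cancel out within the group, so the negative values follow from the positive ones and add nothing. Each same-number pair correlated above 0.1 in the 8 knockdown contrasts, in 4 of 7 line contrasts with siNT (WT against CLIP, F192E, E797R, LECY), in 6 of 7 with siUPF1 (not FE-ER) and in 4 of 7 differences of knockdown effects (WT against CLIP, F192E, E797R, LECY). The main fit held no term for the replicate number, so printed counts, SEs and adjusted p-values are unpaired unless the block is named. These contrasts were treated as paired only in a second fit with the replicate number as a block. That fit is given beside a printed result where it changed a call or moved a count by over 1.5 times. Replicates of a group differed by more than sampling noise in all 48 pairs (chi-square per degree of freedom 3.30 to 15.1).

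The alternatives were DESeq2 1.42.0, RLE scaling, no expression filter, the replicate block, a fit of the groups compared alone, each library left out in turn, and other set definitions, prior counts and a CPM minimum for the set responses. For simulated counts of 16466 genes drawn from the real means and library sizes, the knockdown test in CLIP called 46.3%, 74.6% and 87.9% of genes changed 1.5-, 2- and 3-fold with 5.4% false calls, the WT against CLIP test with siUPF1 called 43.3%, 74.6% and 92.4% with 2.1% false calls, the difference of knockdown effects called 22.4%, 58.2% and 75.8% with 7.1% false calls, and no gene was called where nothing had been changed. In this simulation 67, 67 and 66 genes were changed 1.5-, 2- and 3-fold, in CLIP with siUPF1 alone. Its libraries were drawn independently, without a shared replicate number. The real CLIP knockdown called 5622 genes, so these shares do not carry over to the real data. A planted gene list was recovered by camera (p = 3.34e-129, and 1.96e-24 with an estimated correlation), and 0 of 100 unchanged lists had a p under 0.05. The simulated genes were drawn independently of each other. These lists therefore cannot show whether the preset correlation holds for real lists, whose members may vary together. Markers of other cell types were examined for foreign cells. The highest fibroblast marker was COL3A1 at 5.65 CPM, and SFN, CD14, VWF and APOA1, the highest keratinocyte, leukocyte, endothelial and hepatocyte markers, lay at 0.902, 0.849, 0.881 and 0.17 CPM, while the neural gene NEFL, which 293 cells are known to express, reached 369 CPM.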

Results

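RNA was sequenced from 8 stable Flp-In 293 T-REx lines, each transfected with siNT or siUPF1, in 3 biological replicates per line and siRNA, 48 libraries in all. Libraries held 6016999 to 14551820 expected counts with a median of 8670884, and 16697 genes were tested. UPF1 is the RNA helicase at the centre of NMD, which degrades mRNAs with premature stop codons and a number of normal mRNAs and noncoding RNAs. The lines with CLIP-tagged UPF1 let endogenous UPF1 be knocked down in cells that carry a wild-type or mutant protein, so the knockdown response of each line was read against that of the line with the CLIP tag alone and that of the WT line.

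UPF1 itself (chromosome 19, 18831938 to 18868236, hg38) had 106 ± 7.45 CPM in CLIP cells with siNT and 20.4 ± 0.92 CPM with siUPF1 (SD, n = 3 each), so 19.3% of the RNA was left. The fall was −2.37 on the log2 scale (SE 0.13, adjusted p = 2.1e-17). WT cells held 4059 ± 379 CPM with siNT and 4515 ± 409 CPM with siUPF1 (n = 3 each), 38.4 and 42.7 times the level of CLIP cells with siNT. In the 6 mutant lines the level with siUPF1 ran from 3260 ± 224 CPM in LECY to 4819 ± 261 CPM in FE-ER (n = 3 each). LECY was the mutant whose UPF1 level with siUPF1 differed from WT (log2 difference −0.47, SE 0.11, adjusted p = 0.00283). The siRNA did not lower total UPF1 RNA in any of the 7 lines with CLIP-UPF1, with log2 changes of −0.15 (LECY, adjusted p = 0.342) to 0.15 (WT, adjusted p = 0.404). Since transgene and endogenous reads were summed at this gene, the loss of endogenous UPF1 in those 7 lines could not be read from its level. An exact permutation test of UPF1 in 3 against 3 libraries cannot give a p below 0.1, and it gave 0.1 for CLIP cells with siUPF1 against siNT.

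**Figure D1:**
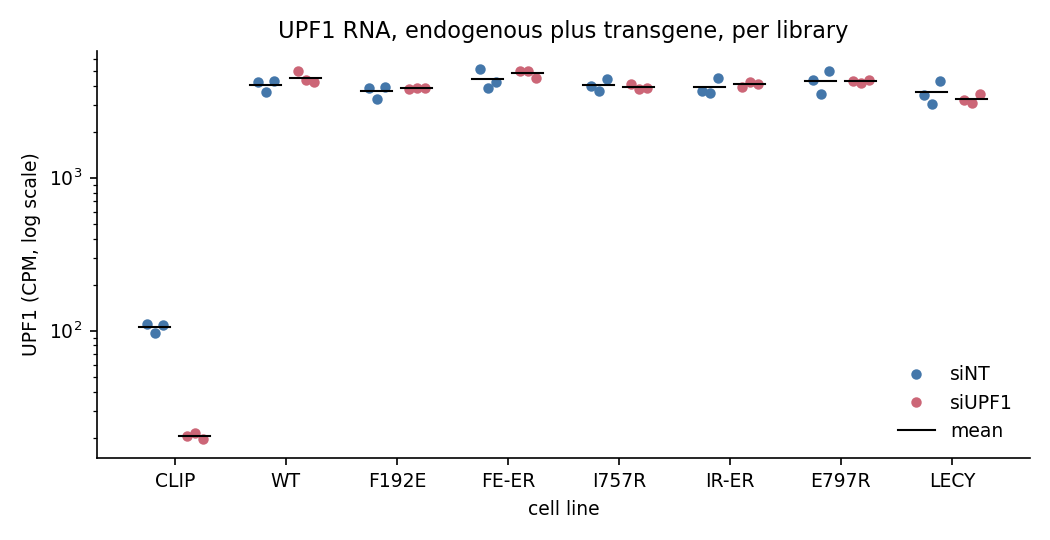
UPF1 level in each library in CPM on a log axis, by line and siRNA, with a bar at the mean of 3 replicates. CLIP cells lay at 106 CPM with siNT and 20.4 CPM with siUPF1, and the group means of the 7 lines with CLIP-UPF1 ran from 3260 to 4819 CPM.

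Knockdown in CLIP cells shows the response to siUPF1 where UPF1 is not put back by a transgene. Of the 10 largest rises 4 were in pseudogenes and 6 in coding genes. The largest was in the pseudogene CCT6P1 (chromosome 7, 65751142 to 65763354), from 2.63 ± 0.536 to 26.3 ± 8.79 CPM (n = 3 each; log2 3.30, SE 0.21, adjusted p = 1.45e-15). RP9P, another pseudogene (chromosome 7, 32916815 to 32943176), went from 6.96 ± 0.208 to 37.1 ± 2.88 CPM (2.41, SE 0.17, 3.7e-14). WASH7P and CCT6P3, also pseudogenes, rose by 2.43 and 2.20. Reads of such copies can be divided wrongly between them and their parent genes. Coding genes among the 10 largest rises were TSC22D3, a glucocorticoid-induced transcription regulator (101 ± 27.3 to 725 ± 78.5 CPM, 2.84, SE 0.56, adjusted p = 0.000141), and C6orf48, a host of snoRNAs (21.3 ± 3.01 to 102 ± 13.9 CPM, 2.25, SE 0.23, adjusted p = 6.5e-10). ZNF185, WNK4, ARRDC4 and SLC44A2 followed with log2 changes of 2.29, 2.28, 2.25 and 2.19. The largest fall was in FADS2, a fatty acid desaturase (chromosome 11, 61792980 to 61867354), from 42.7 ± 9.28 to 2.91 ± 0.0552 CPM (−3.87, SE 0.31, adjusted p = 2.21e-12). PRDX3, a mitochondrial peroxiredoxin (chromosome 10, 119167703 to 119178833), fell from 98.9 ± 8.43 to 10.6 ± 2.36 CPM (−3.21, SE 0.17, adjusted p = 1.06e-17). MAP2K6, a kinase that activates p38 (chromosome 17, 69414698 to 69553861), fell from 43.7 ± 4.84 to 5.81 ± 1.08 CPM (−2.92, SE 0.19, adjusted p = 3.05e-15). MSX1, RIDA, SCART1, NOTCH3, GAMT and KRCC1 fell with log2 changes of −2.99, −2.65, −2.61, −2.39, −2.35 and −2.33. In all, 3017 genes rose and 2605 fell in CLIP, 1571 and 1447 of them by at least 1.5-fold.

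Of the 42 established NMD targets tested in CLIP, 27 rose, 4 fell and 11 did not pass the test. Adjusted over the list alone 28 rose and 5 fell (median log2 change 0.73, camera adjusted p = 4.98e-10, and adjusted p = 0.000245 with an estimated correlation). RASSF1 rose from 12.7 ± 1.20 to 45.3 ± 5.48 CPM (n = 3 each; log2 1.84, SE 0.15, adjusted p = 1.78e-12). The autophagy gene GABARAPL1 rose from 37.8 ± 3.52 to 116 ± 1.17 CPM (1.61, SE 0.14), and the co-chaperone gene BAG1 by 1.78 (SE 0.17). The 4 members that fell, named here after their values were seen, were RPL12, HNRNPDL, RPS9 and TNFRSF10B (−0.64, −0.33, −0.32 and −0.24). NMD factors rose in 9 and fell in 1 of 18 cases, the same numbers when adjusted over the list alone (median 0.30, adjusted p = 0.000359, lost at an adjusted p = 0.275 with an estimated correlation). SMG1, the kinase that phosphorylates UPF1 (chromosome 16, 18804853 to 18926454), rose from 335 ± 31.5 to 982 ± 64.0 CPM (1.55, SE 0.09, adjusted p = 9.03e-17). UPF3B rose from 103 ± 8.61 to 180 ± 9.63 CPM (0.81, SE 0.11), while RUVBL1 fell (−0.62). Among 30 snoRNA host genes, 18 rose and 3 fell over all genes and adjusted over the list alone (median 0.52, adjusted p = 5.85e-08, lost at an adjusted p = 0.0688 with an estimated correlation). SNHG7 rose from 34.0 ± 5.22 to 101 ± 11.8 CPM (1.57, SE 0.10), EPB41L4A-AS1 by 1.51 and SNHG15 by 1.12. SNHG7 is annotated as antisense, so its reads may include those of its partner.

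Stress, translation and cell cycle lists also moved in CLIP. The stress list shares members with the NMD target list, ATF4 among them, so the rises of these 2 lists are not separate results. Of 34 ATF4 integrated stress response genes 19 rose and 3 fell, and 21 rose and 3 fell adjusted over the list alone (median 0.66, adjusted p = 0.000113, lost at an adjusted p = 0.65 with an estimated correlation). The transcription factor gene ATF4 rose from 770 ± 49.1 to 1382 ± 54.1 CPM (n = 3 each; 0.84, SE 0.11), the amino acid transporter genes SLC7A5 and SLC7A1 by 1.53 and 0.85, and the asparaginyl-tRNA synthetase gene NARS fell (−0.91). Of 57 cytosolic ribosomal protein genes 1 rose and 40 fell, and 1 and 44 adjusted over the list alone (median −0.30, adjusted p = 5.36e-10, lost at an adjusted p = 0.414 with an estimated correlation). RPS24 fell from 723 ± 60.5 to 384 ± 38.2 CPM (−0.91), and RPS23 and RPL24 also fell (−0.89 and −0.46). Of 25 cell division genes none rose and 10 fell, 12 adjusted over the list alone (median −0.27, adjusted p = 0.00106, lost at an adjusted p = 0.65 with an estimated correlation), with HMMR, KIF23, AURKA and TOP2A at −1.15, −0.90, −0.55 and −0.47. INA, a neurofilament gene that 293 cells express in part, fell in all 8 knockdowns, from −0.42 in CLIP (adjusted p = 0.0177) to −0.82 in E797R (adjusted p = 9.02e-05). The fibroblast gene COL3A1, at group means of 1.04 to 5.65 CPM, fell in CLIP (−1.40, adjusted p = 0.0103) and rose in I757R (1.16, adjusted p = 0.0255) and E797R (1.48, adjusted p = 0.0126). It was higher in WT than in CLIP with siUPF1 (1.76, adjusted p = 0.00355), and the difference of knockdown effects was 2.51 for WT against CLIP (adjusted p = 0.00787) and −2.12 for LECY against WT (adjusted p = 0.0323). COL1A1, at most at 3.10 CPM, fell in LECY (−1.19, adjusted p = 0.0113) and was lower there than in WT with siUPF1 (−1.55, adjusted p = 0.00214). With siUPF1, PDGFRA was higher in WT than in CLIP (0.88, adjusted p = 0.0444), as was the neural gene NEFM (1.79, adjusted p = 0.0111), which was lower in LECY than in WT (−1.50, adjusted p = 0.0357). TUBB3, another neural gene, fell in WT, IR-ER and E797R (−0.68, −0.67 and −0.84, adjusted p = 0.0333, 0.0254 and 0.00672).

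The other 12 lists did not pass the list test in CLIP. Splicing factors with poison exons split into 7 that rose, among them HNRNPH3 (1.06), RBM39 (0.84) and SRSF10 (0.79), and 16 that fell, among them LUC7L3 (−1.01), of 39 members (7 and 18 adjusted over the list alone, list adjusted p = 0.346). Unfolded protein response genes had 7 rises and no fall among 20 with either adjustment, with HYOU1 at 1.05 (0.0794). Targets of p53 had 1 rise and 7 falls among 24 with either adjustment, led by TP53INP1 at −1.35 (0.126). Replication-dependent histones had 4 rises and 7 falls among 42 and 2 and 1 adjusted over the list alone (0.263). DNA replication genes had 4 and 7 among 25 and 4 and 8 adjusted over the list alone (0.346). Cholesterol synthesis genes had 1 and 9 among 21 with either adjustment, with PMVK at −0.92 (0.0653). Interferon response genes had 2 rises (ISG15 at 1.20) and 5 falls (IFIT1 at −1.93) among 15 (0.713), and mRNA decay enzymes 4 rises and 5 falls (CNOT7 at −1.07) among 27 (0.713), in each case also adjusted over the list alone. Selenoprotein genes had 2 rises among 19 (SELENOW at 1.04) and the exon junction complex 2 rises and 1 fall among 13, with either adjustment, and both lists had an adjusted p of 0.99. In these 2 lists the median (−0.05 and −0.01) was negative, and the mean (0.00 and 0.01) and the direction of the test were positive. Of 13 mitochondrially encoded mRNAs and 9 abundant structural RNAs, read as signs of RNA quality, edgeR called 0 with either adjustment, and both lists had an adjusted p of 0.99 (medians −0.03 and 0.14).

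In the WT line fewer genes changed than in CLIP, and the NMD target list did not pass its test. In WT cells 1407 genes rose and 1165 fell (2281 and 2075 with the replicate block). PAQR6 rose from 1.66 ± 0.578 to 8.84 ± 1.29 CPM (n = 3 each; 2.43, SE 0.34, adjusted p = 1.73e-06). SRPRA, a subunit of the signal recognition particle receptor, rose from 43.5 ± 6.16 to 172 ± 42.1 CPM (1.99, SE 0.16, adjusted p = 3.2e-12), and STMND1 and LMLN by 1.88 and 1.75. PRDX3 fell from 101 ± 10.1 to 17.9 ± 3.11 CPM (−2.50, SE 0.16, adjusted p = 9.46e-15), and STMN3, MSX1 and RIDA fell as well (−2.54, −2.51 and −2.41). Of the 42 NMD targets, ANTXR1 (0.60) and BAG1 (0.71) rose and 3 fell, among them EIF4A2 (−0.48), with the same counts adjusted over the list alone (median −0.07, adjusted p = 0.649). Ribosomal protein genes had 1 rise and 14 falls, 1 and 19 adjusted over the list alone (adjusted p = 8.41e-08, lost at an adjusted p = 0.984 with an estimated correlation), with RPS23 at −0.58 and RPLP0, the gene that rose, at 0.96. Of 24 p53 targets 6 fell, 9 adjusted over the list alone (median −0.27, adjusted p = 0.00184, lost at an adjusted p = 0.0511 with an estimated correlation), led by TP53INP1 (−1.10). Of 20 unfolded protein response genes 4 rose with either adjustment, led by HYOU1 (0.85, list adjusted p = 0.0151, lost at an adjusted p = 0.984 with an estimated correlation). With the block the lists of splicing factors (median −0.08, adjusted p = 0.0181, 0.0973 without it) and cell division genes (−0.11, 0.0185, 0.0973 without it) passed as well. When only the WT groups were fitted, the count of changed genes was 1204.

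In the mutant lines the number of genes that rose with siUPF1 ran from 1358 in I757R to 2645 in LECY. It was 1966 in F192E, 1688 in FE-ER, 1537 in IR-ER and 1392 in E797R. In turn 1682, 1422, 1300, 1302, 1290 and 2272 genes fell in F192E, FE-ER, I757R, IR-ER, E797R and LECY. With the replicate block the totals were 5773 in F192E, 5192 in FE-ER, 4756 in I757R, 4715 in IR-ER and 4583 in E797R. With only the 2 groups of the line fitted they were 1344 in I757R and 1394 in E797R. PAQR6, WNK4, LMLN and ENPP5 recurred among the largest rises and PRDX3, MSX1 and FADS2 among the largest falls. In LECY WASH7P (3.03), CCT6P1 (2.99), RP9P (2.62), FADS2 (−3.71) and MAP2K6 (−2.75) were among the largest changes, as in CLIP. NMD targets rose in 27 and fell in 5 of 42 cases in LECY, 28 and 5 adjusted over the list alone (median 0.70, adjusted p = 3.12e-10, and adjusted p = 0.000288 with an estimated correlation). In F192E 11 rose and 4 fell, 13 and 4 adjusted over the list alone (median 0.27, adjusted p = 0.0106, lost at an adjusted p = 0.256 with an estimated correlation). The list did not pass its test in FE-ER (4 rose, 4 fell, adjusted p = 0.548), I757R (2 and 4, 0.949), IR-ER (3 and 3, 0.681) or E797R (3 and 5, 0.298). Adjusted over the list alone 5, 2, 3 and 3 members rose. Further lists passed with the block: stress response (adjusted p = 0.0121, 0.0568 without it) and unfolded protein response genes (0.0317, 0.0535) in F192E, mitochondrially encoded mRNAs, a sign of RNA quality, in FE-ER (median 0.38, 0.029, 0.0636), splicing factors in IR-ER (0.0101, 0.057) and E797R (0.0237, 0.117), and cholesterol synthesis genes in E797R (0.0299, 0.153).

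No library was shared between the knockdowns of different lines, though same-numbered libraries of different lines deviated together (r across genes of 0.179 to 0.239 between WT and CLIP with siUPF1 and 0.158 to 0.316 between LECY and WT). Of the 3017 genes that rose in CLIP, 2296 also rose in LECY, 1712 in F192E, 1400 in FE-ER, 1214 in IR-ER, 1088 in I757R, 1085 in WT and 966 in E797R, where independent lists would share 478, 355, 305, 278, 245, 254 and 252. Across genes, which are not independent replicates, the log2 changes of CLIP correlated with those of LECY at r = 0.754, with F192E at 0.64, with WT at 0.517 and with E797R at 0.477. In all 8 lines 591 genes rose and 534 fell, 42.0% of the rises and 45.8% of the falls in WT. These included the rises of PAQR6 and SRPRA and the falls of PRDX3, MSX1, RIDA and FADS2. The mean response of the 591 genes was 0.79 ± 0.0179 in CLIP and 0.70 ± 0.049 in WT, and that of the 534 genes −0.92 ± 0.0458 and −0.78 ± 0.0055 (SD, n = 3).

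**Figure D2:**
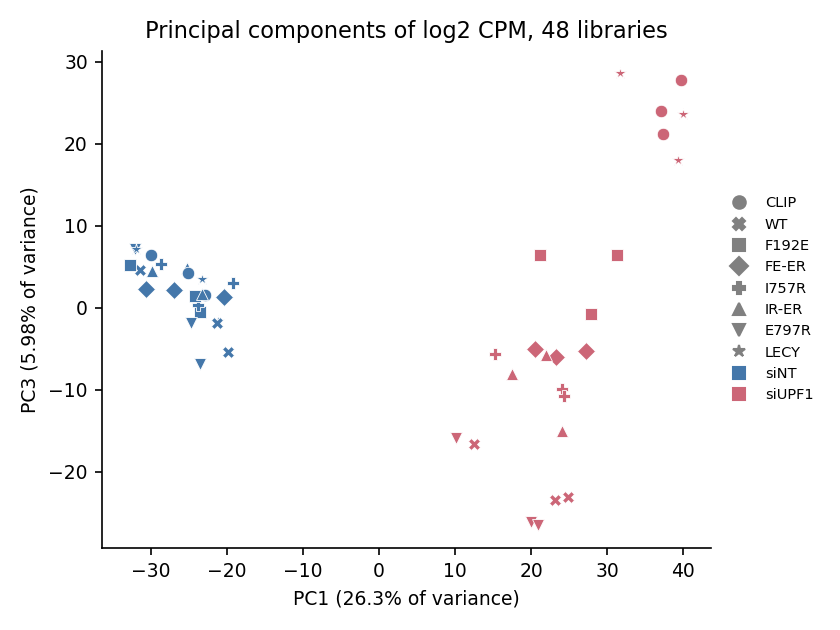
Principal components 1 and 3 of log2 CPM, 1 point per library, coloured by siRNA and shaped by line, with the share of variance on the axes (26.3% and 5.98%). On component 1 siNT libraries lay between −32.7 and −19.2 and siUPF1 libraries between 10.2 and 40.0. On component 3 CLIP and LECY with siUPF1 lay highest, up to 28.6, WT and E797R between −26.5 and −15.9 and the other 4 lines between.

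With siNT, where endogenous UPF1 is present, WT was compared with CLIP and each mutant with WT, and few genes differed. No mutant was compared with CLIP, so what a mutant does against the tag alone was not tested. UPF1 was higher in WT than in CLIP (5.26, SE 0.13, adjusted p = 8.59e-29). CEBPE, a myeloid transcription factor gene, was at 0 ± 0 CPM in WT and 5.86 ± 2.30 CPM in CLIP (adjusted p = 0.000678). In E797R 3 genes were lower than in WT: UPF3B (59.6 ± 7.29 against 90.4 ± 3.41 CPM, −0.60, SE 0.11, adjusted p = 0.0348), NGRN (−0.48, 0.0348) and MED10 (−0.58, 0.0401). GALNT13 was higher in LECY (11.2 ± 1.52 against 4.09 ± 0.536 CPM, 1.45, SE 0.23, adjusted p = 0.00414). LINC02226 was lower in FE-ER (0.996 ± 0.273 against 4.84 ± 0.583 CPM, −2.31, adjusted p = 0.000131) and in IR-ER (0.548 ± 0.194 CPM, −3.13, adjusted p = 7.14e-07). LINC00632, an antisense RNA, was lower in I757R (2.24 ± 0.240 against 7.13 ± 0.657 CPM, −1.67, adjusted p = 0.005). CEBPE, LINC02226 and LINC00632 were chosen after their values were seen. For F192E against WT edgeR called 0 genes, with 323 at an unadjusted p under 0.05, DESeq2 called 2 and the replicate block 2. With the block there were 4 genes for WT against CLIP, 7 for E797R and 6 for LECY. Without the expression filter there were 24 for WT against CLIP and 32, 30, 46, 55, 33 and 33 for F192E, FE-ER, I757R, IR-ER, E797R and LECY. Lists that passed with the block alone were unfolded protein response (adjusted p = 0.0194, 0.0836 without it) and DNA replication genes (0.0234, 0.0836) in F192E, splicing factors (0.0124, 0.0614) and DNA replication genes (0.0174, 0.0614) in E797R and selenoprotein genes in LECY (0.0194, 0.0502). The count fell to 0 in I757R without replicate 1 or 2 of I757R or replicate 2 of WT and was 2 without replicate 1 of WT. With only the groups compared fitted, FE-ER, I757R, E797R and LECY each had 0 genes. In E797R the count was 0 or 1 without any 1 of the 6 libraries, and in LECY it was 0 without replicate 1 or 2 of WT or replicate 2 of LECY.

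With siUPF1, WT was compared with CLIP to see which RNAs depend on UPF1 being put back. CCT6P1 was at 3.42 ± 0.540 CPM in WT and 26.3 ± 8.79 CPM in CLIP (n = 3 each; −2.94, SE 0.21, adjusted p = 1.05e-13), and RP9P, CCT6P3 and WASH7P were lower (−2.26, −2.23 and −2.16). MAP2K6 was higher in WT (28.0 ± 3.66 against 5.81 ± 1.08 CPM, 2.27, SE 0.19, adjusted p = 1.38e-11), as were FADS2 (1.66) and METTL7A (1.55). Of 42 NMD targets 28 were lower in WT and none higher, 30 and 2 adjusted over the list alone (median −0.76, adjusted p = 1.37e-22, and 1.58e-07 with an estimated correlation). RASSF1 was at 14.4 ± 3.50 and GABARAPL1 at 40.4 ± 5.35 CPM in WT (−1.66 and −1.51). NMD factors were lower in 8 and higher in 1 of 18 cases, 8 and 2 adjusted over the list alone (adjusted p = 0.0116 with an estimated correlation). Host genes of snoRNAs were lower in 16 and higher in 0 of 30, 18 and 2 adjusted over the list alone (0.00121 with an estimated correlation). Of 34 integrated stress response genes 13 were lower and 1 higher, 17 and 1 adjusted over the list alone (adjusted p = 3.22e-08, lost at an adjusted p = 0.29 with an estimated correlation). Of 21 cholesterol synthesis genes 8 were higher, among them MSMO1 (0.88) and IDI1 (0.63), and 10 adjusted over the list alone (adjusted p = 0.000848, lost at an adjusted p = 0.29 with an estimated correlation). With the block DNA replication genes (median 0.17, adjusted p = 0.0376, 0.0599 without it) and mitochondrially encoded mRNAs (0.31, 0.018, 0.0599 without it) were also higher in WT as lists. In total 910 genes were higher and 1437 lower in WT (2049 and 2187 with the block, 1421 in all with only the groups compared fitted).

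The difference between the knockdown effects of WT and CLIP removes what differed between the lines with siNT. The log2 effect was higher in WT for MAP2K6 (difference 2.36, SE 0.25, adjusted p = 2.42e-08), FADS2 (1.73) and METTL7A (1.64), and lower for CCT6P1 (−3.27, SE 0.32, adjusted p = 2.78e-09), RP9P (−2.23), STC2 (−2.13) and C6orf48 (−2.12). For 20 of the 42 NMD targets the effect was lower in WT and for none higher, 27 and 0 adjusted over the list alone (median −0.79, adjusted p = 1.15e-23, and 8.62e-08 with an estimated correlation). For snoRNA hosts the counts were 15 and 0 of 30, 16 and 0 adjusted over the list alone (0.00095 with an estimated correlation). The effect was lower for 540 genes and higher for 128 (1044 and 550 with the block, 359 in all with only the 4 groups fitted).

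LECY with siUPF1 differed from WT in pseudogenes, NMD targets and MAP2K6. CCT6P1 was at 22.4 ± 1.09 and 3.42 ± 0.540 CPM (n = 3 each; 2.71, SE 0.21, adjusted p = 1.48e-12), RP9P and WASH7P differed by 2.33 and 2.20. ZFAND2A, a stress-induced zinc finger gene (chromosome 7, 1152071 to 1160759), was at 48.2 ± 5.04 and 11.3 ± 1.38 CPM (2.09, SE 0.14, adjusted p = 6.15e-14). MAP2K6 was lower (6.67 ± 0.720 against 28.0 ± 3.66 CPM, −2.08, SE 0.19), with METTL7A, ASTN1 and FADS2 at −1.56, −1.55 and −1.47. Of the 42 NMD targets 28 were higher and none lower, 28 and 3 adjusted over the list alone (median 0.69, adjusted p = 1.32e-20, and 4.42e-07 with an estimated correlation). NMD factors were higher in 8 and lower in 1 of 18 cases, 8 and 2 adjusted over the list alone (0.0131 with an estimated correlation), with SMG1 at 998 ± 9.21 against 398 ± 33.4 CPM (1.33). Host genes of snoRNAs were higher in 16 and lower in 0 of 30, 16 and 1 adjusted over the list alone (0.000582 with an estimated correlation). In total 1366 genes were higher and 892 lower (2097 and 1977 with the block, 1016 in all with only the groups compared fitted). The knockdown effect differed from that in WT for 461 genes upward and 92 downward (916 and 496 with the block, 218 in all with only the 4 groups fitted), among them CCT6P1 (2.96), WASH7P (2.52), RP9P (2.44), ZFAND2A (2.38), MAP2K6 (−2.19) and METTL7A (−1.75). It included RASSF1 (1.80), SNHG7 (1.56) and SMG1 (1.42). On this difference 18 NMD targets were higher and none lower, 25 and 0 adjusted over the list alone (adjusted p = 1.75e-07 with an estimated correlation).

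F192E differed from WT in fewer genes than LECY did, NMD factors among them. With siUPF1, SMG1 was at 740 ± 55.2 CPM against 398 ± 33.4 in WT (n = 3 each; 0.90, SE 0.09, adjusted p = 9.38e-09). UPF3B was at 179 ± 30.9 against 84.4 ± 4.02 CPM (1.08, SE 0.11, adjusted p = 2.17e-08) and GABARAPL1 at 85.0 ± 6.02 against 40.4 ± 5.35 CPM (1.07, SE 0.14, adjusted p = 2.53e-06). RP9P (1.34), CCT6P1 (1.16) and ZFAND2A (25.2 ± 2.72 against 11.3 ± 1.38 CPM, 1.16) were higher, as was the ceramide synthase gene CERS1 (53.7 ± 4.48 against 22.1 ± 1.45 CPM, 1.28, SE 0.11, adjusted p = 1.52e-09), which lies on the minus strand of chromosome 19 with its 3′ end at 18868545, just past the end of UPF1. TMX1, MAP2K6, IL12RB2 and CAP2 were lower (−0.84, −0.75, −0.70 and −0.69). Of the 42 NMD targets 5 were higher and none lower, 18 and 1 adjusted over the list alone (median 0.22, adjusted p = 1.4e-08, and 0.000726 with an estimated correlation). Of 18 NMD factors 7 were higher and 1 lower with either adjustment (0.0242 with an estimated correlation). Of 30 snoRNA hosts 6 were higher, 11 adjusted over the list alone (0.0325 with an estimated correlation). With the block splicing factors were lower as a list (median −0.11, adjusted p = 0.00953, 0.0529 without it). In total 252 genes were higher and 52 lower (710 and 457 with the block, 85 in all with only the groups compared fitted). The count was 151 without replicate 2 of WT, 174 without replicate 1 of F192E and 200 without replicate 3 of F192E. The log2 knockdown effect was higher than in WT for 30 genes and lower for none (84 and 10 with the block, 2 in all with only the 4 groups fitted), among them RP9P (1.34), ZFAND2A (1.21), EPB41L4A-AS1 (1.11), CERS1 (1.03) and SMG1 (0.98, SE 0.12, adjusted p = 1.78e-05). Without replicate 2 of WT with siNT, replicates 2 or 3 of WT with siUPF1 or replicate 3 of F192E with siNT there were 17, 15, 16 and 14. On this difference NMD targets had 2 members higher, 7 adjusted over the list alone (median 0.29, adjusted p = 0.000244 with an estimated correlation).

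FE-ER differed from WT with siUPF1 in 64 genes upward and 7 downward. SMG9, a subunit of the SMG1 complex, was at 114 ± 7.94 against 64.0 ± 8.89 CPM (n = 3 each; 0.84, SE 0.13, adjusted p = 0.000176), SMG1 at 619 ± 35.9 against 398 ± 33.4 CPM (0.64, SE 0.09), and C6orf48, CERS1, RP9P and GABARAPL1 were higher by 0.97, 0.89, 0.85 and 0.77. DMD, PPIC, CREG1 and C9orf40 were lower (−0.65, −0.52, −0.40 and −0.37). NMD targets were higher in 2 of 42 cases, 3 adjusted over the list alone (median 0.16, adjusted p = 0.00206, lost at an adjusted p = 0.127 with an estimated correlation). The knockdown effect was higher than in WT for SMG1 (0.68, SE 0.12, adjusted p = 0.0372) and called for no other gene. On this difference NMD targets lay higher as a list (median 0.09, unadjusted camera p = 0.000761, and 0.0137 with an estimated correlation). DESeq2 called 129 genes with siUPF1, a fit of only the groups compared called 8, and the count was 18 without replicate 2 and 33 without replicate 3 of WT, and 39, 40 and 30 without replicates 1, 2 and 3 of FE-ER. The SMG1 call on the difference was lost in 9 of the 12 fits that left out a library and in the fit of only the 4 groups compared.

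I757R and IR-ER differed from WT with siUPF1 in fewer genes than FE-ER did in the main fit. Without the expression filter IR-ER had more, 196 against 148 in FE-ER. In I757R with siUPF1 12 genes were higher and 1 lower (54 and 35 with the block): ZFAS1, an antisense snoRNA host (71.9 ± 12.6 against 31.2 ± 6.00 CPM, n = 3 each, 1.20, SE 0.21, adjusted p = 0.003), PKD1P6 (0.84), SMG9 (0.82), DMPK (0.82), SMG1 (603 ± 16.4 CPM, 0.60) and UPF3B (0.55) were among those higher. In IR-ER 29 were higher and 12 lower (163 and 169 with the block), among them ARC (1.40), TNFAIP3 (1.30), ZFAS1 (1.07), RPL22L1 (1.02) and SMG1 (0.58), and C1orf198 (−0.58), GXYLT1 (−0.50), PRNP (−0.49) and TRAFD1 (−0.49). Of the 42 NMD targets 2 were higher in I757R with either adjustment (median 0.09, adjusted p = 0.00116, lost at an adjusted p = 0.0998 with an estimated correlation). In IR-ER 1 was higher, 3 adjusted over the list alone (median 0.16, adjusted p = 4.13e-05, and 0.0336 with an estimated correlation). The knockdown effect differed from that in WT in 0 genes by edgeR in both lines, with 312 and 275 genes at an unadjusted p under 0.05, and in 0 by DESeq2, with 245 and 226. Without the expression filter edgeR called 34 in each line. On this difference NMD targets lay higher as a list in IR-ER (median 0.11, unadjusted camera p = 0.00111, and 0.0169 with an estimated correlation). In I757R the median was 0.05 (unadjusted camera p = 0.0229, and 0.0882 with an estimated correlation). The siUPF1 count of I757R was 6 without replicate 2 of WT and 8 without replicate 3 of I757R, and DESeq2 called 31. Fits of only the groups compared called 0 with siUPF1 in both lines, and 1 on the difference for I757R. The siUPF1 count of IR-ER was 20 and 7 without replicates 1 and 2 of WT, 14, 75 and 10 without replicates 1, 2 and 3 of IR-ER, and 90 by DESeq2.

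E797R with siUPF1 differed from WT in 8 genes, each lower in the mutant. UPF3B was at 52.3 ± 3.69 against 84.4 ± 4.02 CPM (n = 3 each; −0.69, SE 0.11, adjusted p = 0.0021). NGRN was at 188 ± 4.96 against 284 ± 14.1 CPM (−0.60, SE 0.09), C1orf198 at 61.3 ± 1.46 against 94.2 ± 2.97 CPM (−0.62, SE 0.08) and DDX49 at 28.2 ± 6.70 against 44.9 ± 7.55 CPM (−0.68, SE 0.13). UPF3B and NGRN were also lower with siNT. Of the 42 NMD targets 1 was lower with either adjustment (median −0.08, adjusted p = 0.00623, lost at an adjusted p = 0.335 with an estimated correlation). The knockdown effect differed from that in WT in 0 genes by edgeR and 0 by DESeq2, with 273 and 213 at an unadjusted p under 0.05. Without the expression filter edgeR called 18, of which 5 were higher and 13 lower. With the block the lists of the exon junction complex (adjusted p = 0.037, 0.0864 without it), splicing factors (0.0223, 0.0619), mRNA decay enzymes (0.037, 0.0923) and cholesterol synthesis genes (0.037, 0.136) passed with siUPF1. With the block 6 genes were higher and 74 lower, DESeq2 called 40, and a fit of only the groups compared called 0. The count was 3 and 15 without replicates 1 and 3 of WT and 15 and 4 without replicates 2 and 3 of E797R.

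**Figure D3:**
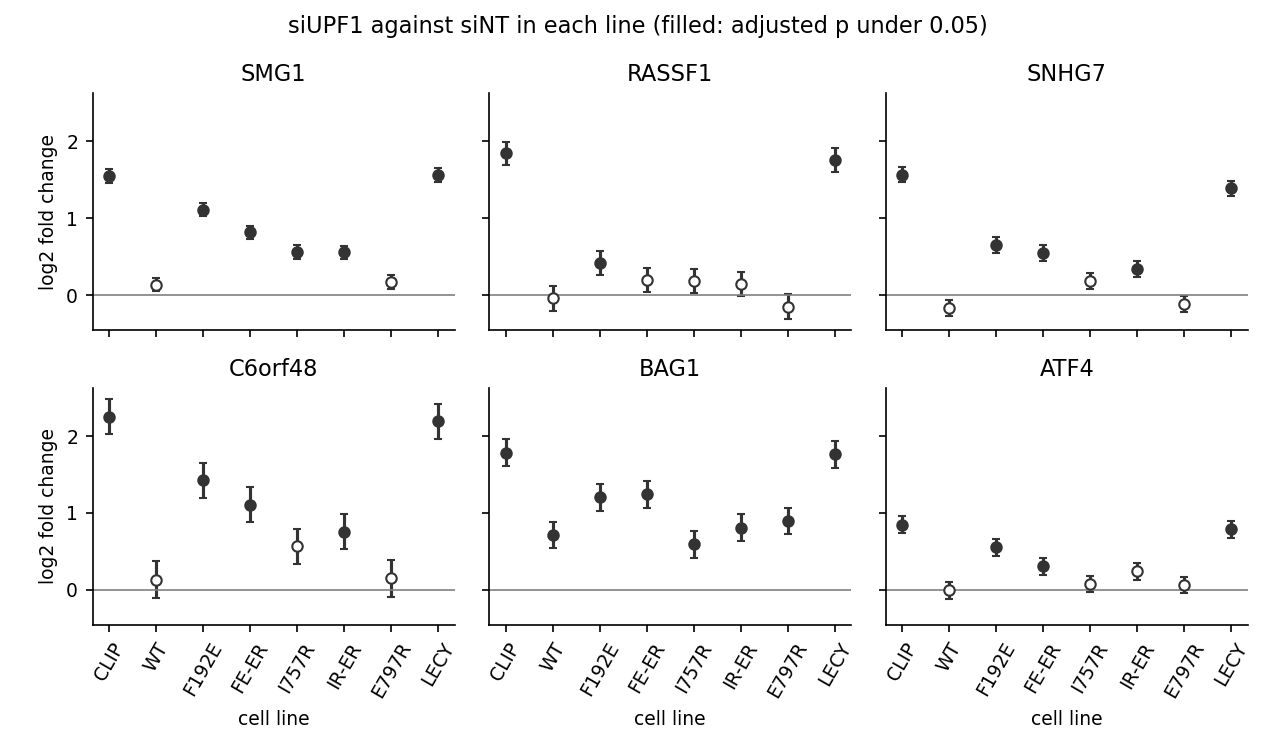
Knockdown effect on SMG1, RASSF1, SNHG7, C6orf48, BAG1 and ATF4 in each line (log2 fold change of siUPF1 over siNT, bars 1 SE, n = 3 against 3), filled where the adjusted p was under 0.05. SMG1 rose by 1.55 in CLIP, 1.56 in LECY, 1.11 in F192E, 0.82 in FE-ER and 0.56 in I757R and IR-ER, while its changes of 0.14 in WT and 0.17 in E797R were not called.

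As 1 value per line, the mean response of the 1571 genes of the UPF1-repressed set was 0.96 ± 0.070 in CLIP and 0.41 ± 0.077 in WT (log2, SD, n = 3), which is 42.8% of CLIP. LECY kept 86.2% (0.83 ± 0.089), F192E 66.0% (0.64 ± 0.067), FE-ER 56.4% (0.54 ± 0.061), IR-ER 49.5% (0.48 ± 0.083), I757R 47.2% (0.45 ± 0.077) and E797R 38.4% (0.37 ± 0.096). The set was chosen on the CLIP libraries, and chosen on 2 replicate numbers and read in the third the response of CLIP was 0.89. The set also takes in genes that rose in all 8 lines, whose median change was 0.73 in CLIP and 0.62 in WT. Its percentages thus hold a part shared by all lines and do not measure rescue alone. On the 42 NMD targets the share of the CLIP response was −6.7% in WT, 94% in LECY, 38.7% in F192E and 14.2% in FE-ER. It was 12.8% in IR-ER, 6.8% in I757R and −12.3% in E797R. Compared as groups of 3, LECY exceeded WT by 0.42 ± 0.048, F192E by 0.22 ± 0.071 and FE-ER by 0.13 ± 0.044, each with non-overlapping replicates and the smallest exact permutation p the design allows (0.1). IR-ER (0.06 ± 0.053, exact p = 0.2), I757R (0.04 ± 0.067, exact p = 0.4) and E797R (−0.04 ± 0.063, exact p = 0.3) overlapped with WT. Taken within replicate numbers, which was added after seeing the data, IR-ER minus WT was 0.06 ± 0.0041, I757R minus WT 0.04 ± 0.019 and E797R minus WT −0.04 ± 0.025, each of 1 sign in 3 of 3 numbers (exact sign-flip p = 0.25, the smallest that 3 numbers allow). By the rule of each same-number pair above 0.1 the numbers paired the libraries for E797R and not for the other 2. That rule rests on the lowest pair (r of 0.048 for I757R and −0.103 for IR-ER). In these 2 lines 35 and 30 of 36 library comparisons were still best with their own number. Their SDs within numbers were also smaller than those between groups, so a pairing was not excluded. IR-ER did not overlap with WT on the genes at least 2-fold higher in CLIP (0.11 ± 0.046 above WT) or with a prior count of 0.5 (0.07 ± 0.052). On 382 genes of the set whose knockdown effect was lower in WT than in CLIP, chosen in part on WT and after seeing the data, neither IR-ER (0.18 ± 0.028) nor I757R (0.15 ± 0.03) did (exact p = 0.1 each). Such sets chosen on 2 replicate numbers and read in the third responded by 0.22 in IR-ER, 0.19 in I757R and 0.06 in WT. The 42 NMD targets, which were not chosen on these data, responded by 0.64 ± 0.047 in CLIP, 0.60 ± 0.048 in LECY, 0.25 ± 0.069 in F192E, 0.09 ± 0.095 in FE-ER, 0.08 ± 0.154 in IR-ER, 0.04 ± 0.051 in I757R, −0.04 ± 0.035 in WT and −0.08 ± 0.088 in E797R.

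**Figure D4:**
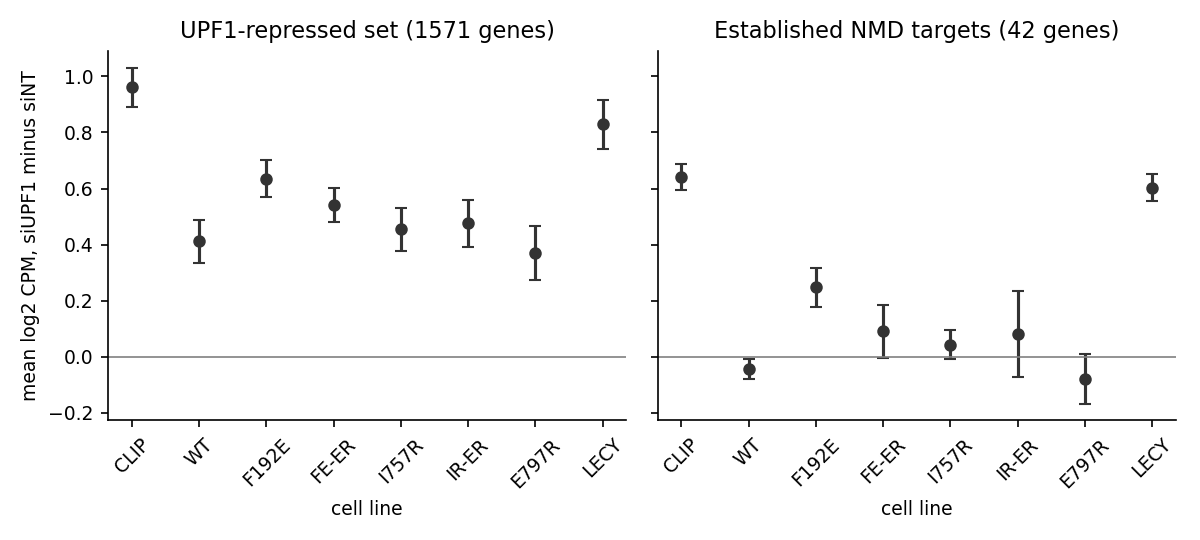
Mean log2 response to siUPF1 by line for the 1571 genes of the UPF1-repressed set and the 42 established NMD targets, with the mean as a point and bars of 1 SD (n = 3). CLIP and LECY lay highest with both (0.96 and 0.83, 0.64 and 0.60), F192E between (0.64 and 0.25), and WT and E797R lowest (0.41 and 0.37, −0.04 and −0.08).

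FE-ER and IR-ER were set beside the single mutants whose labels they share letters with. NMD targets responded less in FE-ER than in F192E (median difference −0.10, adjusted p = 2.39e-05, and 0.0133 with an estimated correlation), with no member called by either adjustment. The structural RNAs, read as a sign of RNA quality, also responded less as a list (median −0.21, adjusted p = 0.0238, 0.0767 with the block, lost at an adjusted p = 0.639 with an estimated correlation). FE-ER exceeded E797R (0.11, adjusted p = 0.000239, lost at an adjusted p = 0.0623 with an estimated correlation), IR-ER exceeded E797R (0.15, adjusted p = 0.00014, and 0.0377 with an estimated correlation) and IR-ER against I757R did not pass (0.04, adjusted p = 0.561). Mitochondrially encoded mRNAs responded more in FE-ER than in E797R (median 0.31, adjusted p = 0.00398, lost at an adjusted p = 0.711 with an estimated correlation), and with the block more in IR-ER than in I757R (0.17, 0.0235, 0.127 without it). The mean response of the UPF1-repressed set in FE-ER minus that in F192E was −0.09 ± 0.065. It was 0.17 ± 0.056 higher in FE-ER than in E797R, 0.11 ± 0.062 higher in IR-ER than in E797R (exact p = 0.1 each) and 0.02 ± 0.067 higher than in I757R (exact p = 0.7). FE-ER minus F192E was −0.05 without replicate 2 of F192E with siNT. IR-ER minus E797R was 0.06 without replicate 3 of E797R with siNT and 0.07 without replicate 2 of IR-ER with siNT, and it overlapped over set members of at least 5 CPM (exact p = 0.2). IR-ER minus I757R turned to −0.02 without replicate 3 of I757R with siNT and to −0.01 without replicate 2 of IR-ER with siNT. For single genes edgeR called 0 in each of the 4 comparisons, with 238, 584, 181 and 269 at an unadjusted p under 0.05 for FE-ER against F192E, FE-ER against E797R, IR-ER against I757R and IR-ER against E797R.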

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

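The tests of how much CLIP-UPF1 RNA F192E held, of replicate numbers, of genes that fell in all 8 lines, of pseudogenes whose parent also rose and of other splits of the libraries were chosen only after the results were seen. The tests of a stronger siRNA effect in F192E and of parent reads at pseudogenes were written before. The rescued set was also defined after seeing the data.

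The knockdown effect differed between lines, by edgeR's test of the difference itself, in 668 genes for WT against CLIP and 553 genes for LECY against WT. It differed in 30 genes for F192E against WT and in 1 gene, SMG1, for FE-ER against WT. MAP2K6 and CCT6P1 were among the largest differences of WT from CLIP and of LECY from WT, and RP9P, ZFAND2A and SMG1 had a higher effect in F192E than in WT. For F192E the count was 17 without replicate 2 of WT with siNT, 15 and 16 without replicates 2 and 3 of WT with siUPF1, and 14 without replicate 3 of F192E with siNT. The SMG1 call for FE-ER was lost, leaving 0 genes, in 9 of 12 fits with a library left out. These were the fits without replicate 1 or 2 of WT with siNT, any of the 3 WT replicates with siUPF1, replicate 2 or 3 of FE-ER with siNT, or replicate 1 or 2 of FE-ER with siUPF1.

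Fits of only the 4 groups compared gave 359 genes for WT against CLIP, 218 for LECY, 2 for F192E, 1 for I757R and 0 for FE-ER, IR-ER and E797R. In 40 splits that exchanged lines within each siRNA, the real one included, 5 gave as many genes for WT against CLIP (highest other 767) and 5 for LECY (highest other 636). As many genes came from 7 splits for F192E (highest other 26), 2 for I757R (4), 40 for FE-ER (6), 40 for IR-ER (3) and 40 for E797R (0). Chance was not excluded by this count in any of the 7 differences. The highest other splits for WT against CLIP, LECY and F192E kept the siUPF1 libraries in their lines and exchanged siNT libraries. Such splits leave the difference between lines with siUPF1 in place, so their counts could not decide on chance. For WT against CLIP and LECY the 4 other splits as large kept the siUPF1 libraries in their lines. The 35 splits that exchanged siUPF1 libraries gave at most 0 genes for WT against CLIP and 1 for LECY, but up to 5 for F192E, where 2 of them gave as many as the real split, a comparison added after the split counts were seen.

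In F192E part of the UPF1-repressed set responded more than in WT: the rescued set, 382 genes whose knockdown effect was lower in WT than in CLIP, responded by 0.52 ± 0.027 in F192E, 0.059 ± 0.032 in WT and 1.06 ± 0.081 in CLIP (SD, n = 3). Sets chosen in this way on 2 replicate numbers, of 282, 209 and 154 genes, and read in the third responded by 0.55 ± 0.075 in F192E, 0.06 ± 0.024 in WT and 1.10 ± 0.22 in CLIP (SD, n = 3). A lower amount of CLIP-UPF1 RNA was argued against, because F192E exceeded I757R by 0.353 ± 0.0668 in these sets with UPF1 at 3839 ± 34.9 and 3909 ± 153 CPM with siUPF1. The excess over WT in the sets read in the third number was 0.484 ± 0.0927 and appeared in 3 of 3 replicate numbers. In the 591 genes that rose in all 8 lines F192E minus WT was smaller, at 0.0263 ± 0.0812, as predicted without a stronger siRNA effect. But these genes had to be called in both lines, which favours a similar response, and their rise may come from siNT. The 534 genes that fell in all 8 lines fell further in F192E (F192E minus WT −0.0634 ± 0.0286). Loss of endogenous UPF1 could not be read in either line, so a stronger siRNA effect was not excluded. Reduced activity of the F192E protein in NMD may explain the pattern as a hypothesis, and the protein level, which was not analysed here, stays open.

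Pseudogenes made up 13.6% of the rescued set and 7.1% of the tested genes (odds ratio 2.1, Fisher's exact p = 6.98e-06), with CCT6P1, CCT6P3 and RP9P among them, and 7.6% of the UPF1-repressed set from which it was taken (odds ratio 1.09, Fisher's exact p = 0.41). Of the 591 genes that rose in all 8 lines 1% were pseudogenes (odds ratio 0.129, Fisher's exact p = 1.42e-12). Of the 534 genes that fell in all 8 lines 0.2% were (odds ratio 0.0236, Fisher's exact p = 3.07e-16). The low share was thus not particular to genes that rose. Both sets hold only genes called in all 8 lines, and the Fisher tests did not match genes on expression level. In the UPF1-repressed set, pseudogenes rose more than coding genes in CLIP (median 1.12 against 0.85) and less in WT (0.17 against 0.43). Leaving out genes still raised in WT can therefore raise the share of pseudogenes. Parents were guessed from the symbols, without the final P and number (CCT6A for CCT6P1). For the 25 of 52 with a tested parent, the 20 parents had a median log2 change of 0.126 in CLIP (95% bootstrap interval −0.155 to 0.607) and the pseudogenes 1.37 (1.22 to 1.74). This gap was as predicted without parent reads counted at pseudogenes. But the pseudogenes had been chosen by a rise of at least 1.5-fold in the same CLIP libraries and the parents had not. Part of the gap was thus set by the choice, and parent reads were not excluded. The 11 whose parent also rose exceeded it by a median of 0.602 (0.178 to 0.947 over 8 parents). A fixed share of parent reads would bring no excess, but the same choice favours one. For 4 of them (CLUHP3, PKD1P1, PKD1P6 and SMG1P5) the excess was no more than 2 SE. There parent reads and a change of the pseudogene itself cannot be told apart, because the counts do not separate the copies. Decay of pseudogene RNAs through UPF1 stays open as an untested hypothesis.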

How the results depend on the processing

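The rescued set, the same set chosen on 2 replicate numbers and read in the third, that way of choosing the UPF1-repressed set for lines other than CLIP, the set alternatives for FE-ER and IR-ER against single mutants other than the 2-fold set, differences of set responses within replicate numbers and, for line contrasts, fits of only the groups compared were chosen after seeing the data. RLE scaling kept 29 of 29 counts of changed genes within 1.5 times, and UPF1 levels kept their calls under each alternative run. The replicate block, read as a paired fit where the numbers pair the samples, moved 23 counts. It raised the knockdown totals to 4356 in WT, 5773 in F192E, 5192 in FE-ER, 4756 in I757R, 4715 in IR-ER and 4583 in E797R. With siNT it gave 4 genes for WT against CLIP and 2, 2, 3, 7 and 6 for F192E, I757R, IR-ER, E797R and LECY against WT. With siUPF1 it gave 4236 for WT against CLIP and 1167, 436, 89, 332, 80 and 4074 for F192E, FE-ER, I757R, IR-ER, E797R and LECY. The differences of knockdown effects became 1594 for WT against CLIP, 94 for F192E, 5 for FE-ER and 1412 for LECY. Some contrasts missed the rule of each same-number pair above 0.1. They were FE-ER, I757R and IR-ER with siNT, FE-ER with siUPF1 and the differences of FE-ER, I757R and IR-ER. There the lowest same-number correlations were 0.044, 0.07, −0.099, 0.087, 0.041, 0.048 and −0.103. The mean ones were 0.226, 0.293, 0.178, 0.207, 0.238, 0.271 and 0.21. As a hint from the data, 4, 6, 4 and 6 of 6 libraries of the first 4 correlated best with their own number. For the differences 31, 35 and 30 of 36 library comparisons did. The rule rests on the lowest pair, so missing it does not show that these libraries are unpaired. The block brought 31 gene list tests past the threshold, none of which passed with an estimated correlation without it (adjusted p = 0.553 to 0.984), and 60 tests of named genes whose values are not printed here. In the contrasts that missed the rule, these lists were selenoproteins (FE-ER), cell division genes and mitochondrial mRNAs (I757R) and mitochondrial mRNAs (IR-ER) with siNT, and cholesterol synthesis genes (FE-ER) with siUPF1. On the differences they were splicing factors, unfolded protein response genes and mitochondrial mRNAs (FE-ER), cell division genes and mitochondrial mRNAs (I757R) and stress response genes (IR-ER). In the 4 comparisons with single mutants it ended the call of structural RNAs for FE-ER against F192E (adjusted p = 0.0238, 0.0767 with the block). For IR-ER against I757R unfolded protein response genes and mitochondrial mRNAs passed (0.0358 and 0.0235). These tests are not among the 31 above, and their values with an estimated correlation are not reported here. Whether the numbers pair the libraries was not examined for these 4 comparisons. The block changed no other call.

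Without the expression filter, siNT counts were 24 for WT against CLIP and 32, 30, 46, 55, 33 and 33 for F192E, FE-ER, I757R, IR-ER, E797R and LECY against WT. With siUPF1 they were 148, 103, 196 and 40 for FE-ER, I757R, IR-ER and E797R, and for differences of knockdown effects 87, 26, 34, 34 and 18 for F192E, FE-ER, I757R, IR-ER and E797R. DESeq2 called 2 genes each in F192E, I757R and LECY with siNT and 129, 31, 90 and 40 in FE-ER, I757R, IR-ER and E797R with siUPF1. Fits of only the groups compared gave knockdown totals of 1204 in WT, 1344 in I757R and 1394 in E797R. They had fewer samples to estimate the spread, and the expression filter was applied anew to those samples. With siUPF1 they gave 1421 for WT against CLIP, 85 for F192E, 8 for FE-ER, 0 for I757R, IR-ER and E797R and 1016 for LECY. With siNT they gave 0 for FE-ER, I757R, E797R and LECY. The differences of knockdown effects became 359 for WT against CLIP, 2 for F192E, 0 for FE-ER, 1 for I757R and 218 for LECY. For the counts moved by the block, the filter or DESeq2 the cause was not tested.

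Leaving out 1 library moved 45 of 216 counts. Ranges were 0 to 2 for I757R with siNT, 0 to 1 for E797R and 0 to 1 for LECY. With siUPF1 they were 151 to 246 for F192E, 18 to 88 for FE-ER, 6 to 19 for I757R, 7 to 75 for IR-ER and 3 to 15 for E797R, and the lowest counts of the first 4 came without replicate 2 of WT. The count of 75 came without replicate 2 of IR-ER, and 3 and 15 for E797R without replicate 1 of WT and replicate 2 of E797R. The difference of knockdown effects ranged from 14 to 32 genes for F192E and from 0 to 1 for FE-ER. Fewer samples lower the power of such fits. Over these fits 365 tests of named genes lost their call, 33 gained one and 6160 did neither, and none turned its direction.

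Mean responses depended on the set. In the order CLIP, WT, F192E, FE-ER, I757R, IR-ER, E797R and LECY, genes at least 2-fold higher in CLIP responded by 1.34, 0.51, 0.85, 0.71, 0.59, 0.62, 0.47 and 1.15. The fixed list of NMD targets responded by 0.64, −0.0428, 0.25, 0.0913, 0.04, 0.0821, −0.079 and 0.60, so its sign turned in WT and E797R. The rescued set, chosen in part on WT, responded by 1.06, 0.059, 0.52, 0.35, 0.21, 0.23, 0.074 and 0.95, and sets chosen that way on 2 replicate numbers and read in the third responded by 1.10, 0.0623, 0.55, 0.35, 0.19, 0.22, 0.0608 and 1.03. The UPF1-repressed set chosen that way gave 0.89 in CLIP. FE-ER against F192E was −0.17 on the rescued set, and FE-ER against E797R was 0.27 on it and 0.24 on the 2-fold set. These differences follow from which genes a set holds. With an estimated correlation 145 gene list tests lost their call and 377 did not change. At 6016999 to 14551820 counts per library and 3 replicates, 22.4% of simulated 1.5-fold differences of knockdown effects between WT and CLIP were recovered. That simulation changed few genes and held no shared replicate number, so the share does not carry over to the real data.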

Other observations

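The tests of UPF1 RNA in the WT line, of genes without a site and of other splits of the libraries were chosen only after the results were seen. So were the joined octamers and the look at named genes with a site, while the tests of short sequences in 3′ UTRs were written before.

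Targets of p53 fell with siUPF1 in several lines. In IR-ER 10 of 24 fell and none rose with either adjustment, adjusted over the list alone included (median −0.31, camera adjusted p = 0.000278, and adjusted p = 0.0173 with an estimated correlation). TP53INP1, a p53-induced gene, was at 7.88 ± 1.65 CPM with siUPF1 and 16.6 ± 1.72 CPM with siNT (n = 3 each, −1.08, SE 0.15). RRM2B, a ribonucleotide reductase subunit, the death receptor TNFRSF10B and the DNA polymerase POLH were at −0.81, −0.46 and −0.50. In I757R 7 fell, 8 adjusted over the list alone (median −0.26, adjusted p = 0.000747, and adjusted p = 0.0274 with an estimated correlation). In F192E, FE-ER and E797R 8, 8 and 7 fell, 9, 9 and 7 adjusted over the list alone, and the list call was lost at adjusted p = 0.143, 0.0811 and 0.0991 with an estimated correlation. In LECY 1 rose and 8 fell with either adjustment, and the list did not pass (adjusted p = 0.164).

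With siNT no p53 target was called in any of the 7 line contrasts by edgeR with either adjustment, and the list test still differed. The list lay lower in WT than in CLIP (median −0.15, adjusted p = 0.00115 with an estimated correlation). It lay higher than in WT in F192E (0.16), FE-ER (0.13), I757R (0.10) and IR-ER (0.08), with adjusted p = 0.000359, 0.00553, 0.0047 and 0.0384 with an estimated correlation. In LECY the call was lost at an adjusted p = 0.185 with an estimated correlation, and E797R did not pass (−0.08, adjusted p = 0.0614). All 7 contrasts share the 3 WT libraries with siNT. Cell division genes also fell with siUPF1, 8 of 25 in F192E and 9 in FE-ER with no rise. Adjusted over the list alone 13 fell and 1 rose in F192E and 14 fell and 2 rose in FE-ER (adjusted p = 0.000271 and 0.000282, lost at adjusted p = 0.55 and 0.899 with an estimated correlation).

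The 534 genes that fell and the 591 that rose in all 8 lines were searched for short sequences in 3′ UTRs of at least 30 nt, which 13060 tested genes had. All 16384 heptamers were ranked in 1 random part of the genes, over 10 strata of UTR length, and the best was tested in the other part. A planted heptamer was chosen in 10 of 10 simulated sets, and 1 of 10 sets with nothing planted gave a lower bound above 1.5. In genes that fell the best was GAACATA, with an odds ratio of 4.14 (95% interval 3.08 to 5.57), followed by the overlapping AGAACAT (3.90). The joined octamer AGAACATA lies in the UPF1 mRNA, at chromosome 19, 18852232 to 18852239 (hg38), in exon 6 of UPF1-201 and its coding sequence. Of all octamers 7.32% occur in that mRNA. In genes that rose the best was AGCAACC, with an odds ratio of 3.28 (2.36 to 4.57), and the joined octamer AGCAACCA was not found in the UPF1 mRNA. Genes with GAACATA had a median change below that of genes without it by −0.23 in CLIP and −0.15 in WT, and genes with AGCAACC one above by 0.12 in both. These medians were not adjusted for UTR length. The GAACATA shift differed between lines, from −0.228 in CLIP (95% bootstrap interval −0.268 to −0.175) to −0.094 in E797R (−0.128 to −0.0647). The AGCAACC shift ran from 0.0997 in FE-ER to 0.143 in E797R.

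The changes shared by all 8 lines have a candidate explanation in seed matches of the siRNAs, which bind 3′ UTRs as a microRNA does, with siUPF1 lowering genes with GAACATA (odds ratio 4.14) and siNT lowering genes with AGCAACC (3.28), so that the latter appear to rise. The siRNA sequences were not given in the sources used here. Too little CLIP-UPF1 RNA in WT was argued against by a level 42.7 times that of CLIP cells with siNT. Functions of UPF1 that the tagged protein does not replace cannot be told apart from this. The 45.6% of fallen and 69.7% of risen genes without either heptamer of their set may also change downstream of others. Either heptamer was also present in 19.1% and 11.3% of the other genes searched. A site alone thus does not settle the cause, and these functions stay open for genes with a site too. Of the named genes, PRDX3, RIDA, LOX and KRCC1 among 10 that fell and SRPRA, ENPP5 and LMLN among 10 that rose carried a site, and FADS2 and MSX1 did not.

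Splits of 3 against 3 libraries number 10, too few for a share under 0.05. In fits of only the groups compared, the knockdown changed 5618 genes in CLIP, 1204 in WT, 3159 in F192E, 2703 in FE-ER, 1344 in I757R, 2187 in IR-ER, 1394 in E797R and 3659 in LECY. The highest other split gave 0 in each, so 1 split, the real one, gave as many. With siUPF1 the real and highest other counts were 1421 and 0 for WT against CLIP, 85 and 67 for F192E and 1016 and 2 for LECY, and 1 split gave as many. For FE-ER they were 8 and 389, and 2 splits gave as many. For I757R, IR-ER and E797R the real count was 0, which all 10 splits reached, with highest others of 152, 551 and 5. With siNT the real and highest other counts were 2 and 88 for WT against CLIP, where 4 splits gave as many, and 1 and 2213 for IR-ER, where 3 did. For F192E, FE-ER, I757R, E797R and LECY the real count was 0, which all 10 splits reached, with highest others of 1168, 1847, 1481, 1 and 666. The number of genes at an unadjusted p under 0.05 was not recorded for these edgeR fits.

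The highest splits of F192E, FE-ER, I757R and IR-ER with either siRNA, of LECY with siNT and of E797R with siUPF1 put replicate 3 of WT with replicates 1 and 3 of the mutant. That points to a structure of the samples by replicate number. On principal component 2 (13.8% of variance) the 16 libraries of replicate 2 lay between −31.3 and −9.7 and those of replicate 3 between −1.4 and 36.2, while those of replicate 1 lay between −16.7 and 19.2 and overlapped with both. Among contrasts treated as paired, the other splits that part all 3 pairs as the real one does gave at most 4 genes for I757R, 1 for IR-ER, 1 for E797R and 0 for the other 3 with siUPF1, and 2 for WT against CLIP, 0 for F192E and LECY and 1 for E797R with siNT. With the replicate block the counts with siUPF1 were 1167 for F192E, 89 for I757R, 332 for IR-ER and 80 for E797R, and with siNT 4 for WT against CLIP, 2 for F192E, 6 for LECY and 7 for E797R.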
